A study of Papaver somniferum with 4 samples.

How the data were processed

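Single-colour NimbleGen oligonucleotide arrays, labelled with Cy3, were used to profile total RNA of opium poppy (Papaver somniferum, cultivar Ofis 95). The labels describe 4 samples: a control and plants taken 0, 3 and 12 h after the treatment. Each sample has 3 array files, so 12 arrays of 1 slide were read. Nothing in the labels says whether the 3 arrays of a sample carry RNA of separate plants, so p-values here measure only the spread between arrays of a sample, which may be technical. The tissue is given both as leaves with fruits and as capsule, and the labels do not settle which of these each array carried.

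Each array file holds 1 intensity per sequence for 95608 sequences, 1 probe per sequence, on a linear scale as deposited, and RMA is the only tool named, per the submitters' processing notes. The scanner settings, the RMA software and its version are not given in the sources used here. RMA commonly ends with quantile normalization, which gives all arrays 1 distribution. The deposited intensities do not share a distribution: array medians ran from 343.9 to 482.4. A further row pools 45055 random control probes into 1 intensity per array and was used as the background level, outside all tests. Of the sequences, 19100 have identifiers of expressed sequence tags (ESTs) and 76508 are numbered reads of 1 sequencing run. The latter are named here by their read number. The authors also deposited a table of log2 values with 1 column per sample. Its 4 columns all have a median of 8.69 and maxima from 12.45 to 13.68. How the arrays of a sample were combined is not stated, and was found by regressing each column on the 12 arrays after quantile normalization. Scale and combination were thereby settled, since the means of 3 arrays matched each column to within 0.081 log2 units.

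No sequence could be given a gene name. The annotation column of the array files is empty, and 0 of the 95608 identifiers matched the 91581 genes of the RefSeq table for assembly ASM357369v1. The 15 gene lists fixed before the data were examined, which covered alkaloid, jasmonate, defence, tissue marker and reference genes, could therefore not be tested, and averaging per gene was not possible. The rule for named sequences, also fixed beforehand, then allowed 2 identifiers that rose and 2 that fell per comparison. None passed the threshold, so the 2 with the highest and the 2 with the lowest moderated t of each time point against control are given as values. This use of the moderated t was chosen after the calls were seen, as were the 2 bright ESTs described in the report. Where a named sequence was above the random probes on no array of a group, its differences from the fit are measured values only. Against control, a bound is given beside them as at least N-fold, with that group's values raised to each array's random probes. The bound allows for the background only, not for the spread between arrays, so leaving out an array can take a difference below it.

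Each array was placed in the group of the sample its file is attached to. The deposited intensities were taken to log2 with no further normalization and fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), with all 12 arrays in 1 fit, and adjusted by Benjamini-Hochberg within each comparison. The threshold was an adjusted p of 0.05, with and without a 2-fold change. A moderated F test asked for any difference between the 4 groups. Each SE of a difference is the moderated one of this fit. It pools the spread within all 4 groups and is drawn toward that of the other sequences (prior df 17.6, residual df 8). It can therefore be smaller or larger than the SDs of the 2 groups compared would give. The median standard error of a log2 difference between groups of 3 arrays was 0.56, so its 95% interval reached 1.15 log2 units to either side, or 2.23-fold. The fit was tested on simulated data for 12 h against control, with normal errors and 200 changed sequences among 95608. Each sequence kept its moderated spread from the real fit. It recovered 100% of the 16-fold, 82% of the 8-fold, 20% of the 4-fold and 4% of the 2-fold changes, 50 of each. Of its 119 calls 16 were false, or 13.4%, above the nominal rate. With spreads drawn from the fitted prior 6 of 83 calls were false, or 7.23%. The fit may thus be liberal, but each setting was simulated a single time with normal errors, so the rate in the real data stays open. The simulated comparison without changed sequences gave 0 calls.

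Alternatives fixed beforehand were quantile normalization, median centring, 2 filters on dim sequences, a trended and robust prior, array weights, fitting only the groups compared, slide position as a covariate, a stricter adjusted p of 0.01, the deposited table of log2 values and leaving out each array. The arrays as grouped in the deposited table were added after seeing the data. Likeness of arrays was measured by Spearman's rho across sequences, and within-sample likeness was tested exactly over all 15400 splits of 12 arrays into 4 groups of 3. The 3 comparisons against control share the control arrays, so the covariance of their differences was set against 20 simulations of unchanged groups. Depth has no counterpart on arrays, where the number of arrays limits the precision. All arrays lie on 1 slide and, as the files are attached, each group occupies neighbouring positions, so position and group are then largely confounded.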

Results

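Opium poppy makes morphine, codeine and other benzylisoquinoline alkaloids, and methyl jasmonate is a plant hormone ester that is widely used to elicit defence metabolism. The series asked how the transcriptome of the poppy cultivar Ofis 95 responds when alkaloid biosynthesis is induced. Greenhouse plants past flowering were pricked with pins and sprayed with 100 µM methyl jasmonate. Control plants received the same solvent, ethanol with 0.1% of the detergent Triton X-100, and the labels do not say whether they were pricked. RNA from the control and from 0, 3 and 12 h after treatment was hybridised to 3 arrays per group, 12 in all, each with 95608 poppy sequences.

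The sequences gave about the same intensity as the random control probes on all 12 arrays. Their median differed from the random probes by at most 0.018 log2 units on any array. Between 49.9% and 51.1% of the sequences lay above the random probes. The share at least 2-fold above them was 8.85% ± 1.44 in the control, 11.2% ± 4.27 at 0 h, 12.0% ± 0.92 at 3 h and 14.7% ± 3.50 at 12 h (SD, n = 3 arrays). The higher mean at 0 h came from the array at position 5, at 16.09%. Positions 4 and 6, at 8.75% and 8.64%, lay within the control arrays' range of 7.28% to 10.11%. At 12 h the shares were 18.27%, 11.28% and 14.53% at positions 10, 11 and 12. The ESTs and the read-derived sequences did not stand apart in their level against the random probes. The EST median lay from -0.009 to 0.021 log2 units from the random probes over the 12 arrays, and the read-derived median from 0.001 to 0.02. One 12 h array, at slide position 10, had 6.61% of its sequences at least 4-fold above the random probes, against 0.53% to 2.08% on the other 11 arrays. Intensities over 60000, near the ceiling of the scale, occurred 160 times over the 12 arrays, 69 of them on the control array at position 3 and 42 on the 12 h array at position 10.

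**Figure D1:**
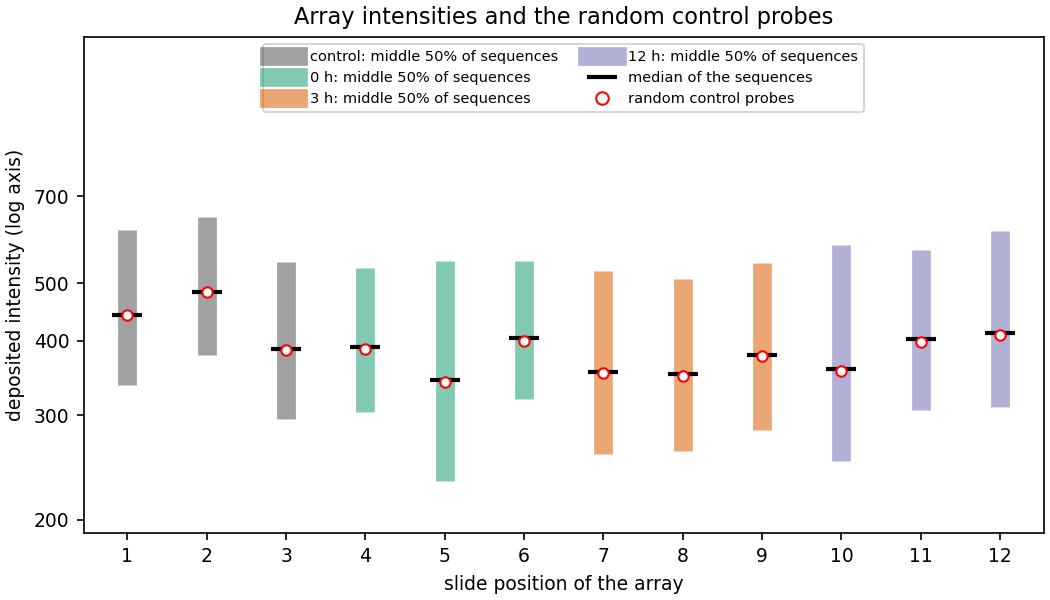
Deposited intensity (log axis) of each array by slide position: bars span the middle 50% of the 95608 sequences, coloured by group, black lines are their medians and red circles the pooled random control probes. Medians run from 343.9 to 482.4, and each lies within 0.018 log2 units of its array's random probes.

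Sequences bright on one array were rarely bright on another. Spearman's rho across sequences had a median of 0.031 over the 66 pairs of arrays and ranged from -0.034 to 0.104. The highest value was between a control and a 0 h array. Pearson's r of the log2 values gave a median of 0.033 and a range from -0.037 to 0.108. These correlations are across sequences, which are not independent replicates. The 12 pairs from 1 sample had a mean rho of 0.0417 and the 54 pairs from different samples 0.0262. Of the 15400 splits of the arrays into 4 groups of 3, 346 gave a mean within groups as large (exact p = 0.0225, one-sided). Arrays of a sample were also neighbours on the slide, and rho fell with distance between positions (rank correlation -0.31 over 66 pairs, p = 0.0157 by 100000 permutations of the arrays, one-sided). Among arrays at most 2 positions apart, the mean rho was 0.0417 for 12 pairs from 1 sample and 0.0315 for 9 pairs from different samples.

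**Figure D2:**
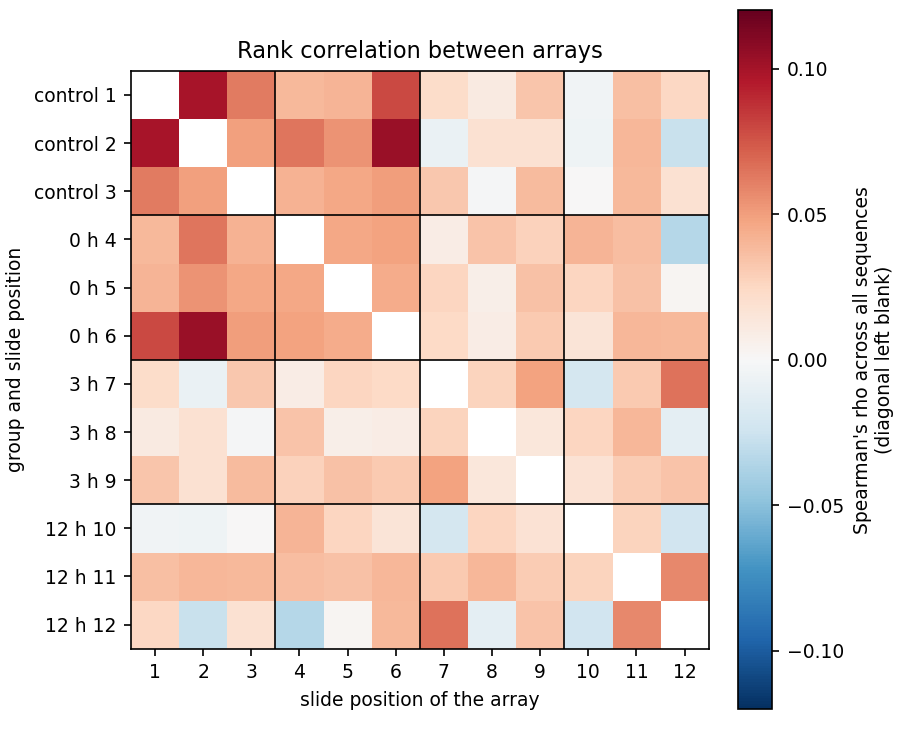
Spearman's rho between each pair of the 12 arrays across 95608 sequences, ordered by slide position, with lines between the groups and a colour scale from -0.12 to 0.12. Values range from -0.034 to 0.104 over the 66 pairs, with a median of 0.031.

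The authors' deposited table of log2 values did not combine the arrays as the files are attached to the samples. Its control column equalled the mean of the quantile-normalized arrays at positions 1, 5 and 9 (r = 0.99998), while the control files are those at positions 1, 2 and 3 (r = 0.411 with the column). Its 0 h column was built from positions 2, 3 and 4 in place of 4, 5 and 6. Its 3 h column was built from positions 6, 7 and 8 in place of 7, 8 and 9. Its 12 h column used positions 10, 11 and 12, as the files do. In all, 7 arrays have the same group in both sources and 5 do not. Under the table's grouping, arrays of a sample had a mean rho of 0.0322 and arrays of different samples 0.0283 (exact p = 0.2836 over the 15400 splits, one-sided). The labels do not say which assignment is right. The comparisons below follow the files, and values from the table are named as such.

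**Figure D3:**
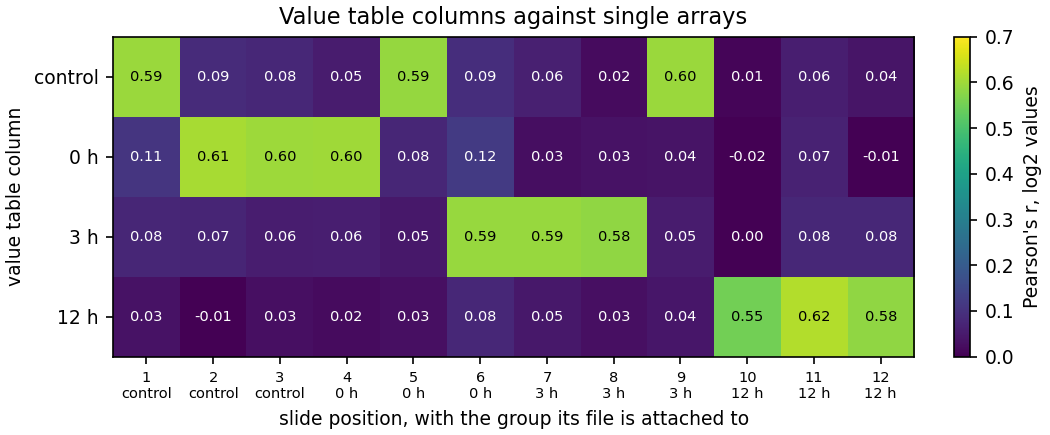
Pearson's r of log2 values between each column of the authors' deposited table (rows) and each array (columns, with slide position and the group its file is attached to). Each column correlates with 3 arrays at 0.55 to 0.62 and with the other 9 at up to 0.12, and the 3 arrays differ from the attached ones for control, 0 h and 3 h.

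At 0 h no sequence passed the test against the control. None of the 95608 passed an adjusted p of 0.05 in limma, and the lowest adjusted p was 0.9997. In the simulated comparison of 12 h with control, the same test recovered 4% of 2-fold and 20% of 4-fold changes, so differences of this size were mostly not detectable with 3 arrays per group. Without adjustment 3979 sequences had a p under 0.05, where chance gives 4780, and alternatives that kept all sequences gave 2536 to 5711, on both sides of that number. The highest moderated t belonged to read 96977, at 7.95 ± 0.38 log2 units in the control and 10.97 ± 2.12 at 0 h (SD, n = 3 arrays), a difference of 3.02 ± 0.70 (SE) that was 1.83 without the 0 h array at position 5. Its control values were not above the random probes on any array, so no exact fold can be given. With them raised to the random probes, the mean of all 3 arrays at 0 h was at least 4.62-fold higher. This bound includes the array at position 5 and does not allow for the spread between arrays. Read 52637 differed by 2.81 ± 0.65, or by 1.79 without the 0 h array at position 4. At the other end, read 57366 was at 12.11 ± 1.57 in the control and 8.58 ± 0.85 at 0 h (SD, n = 3 arrays). Its difference was -3.52 ± 0.68 (SE), or -2.64 without the control array at position 3. Read 34882 differed by -2.96 ± 0.56. Read 34882 was not above the random probes on any 0 h array, and its control mean was at least 4.78-fold higher. All 4 had an adjusted p of 0.9997. In the authors' deposited table the differences of reads 96977, 34882 and 57366 had the opposite sign, at -1.76, 1.40 and 0.89, and that of read 52637 was 0.18.

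At 3 h, again, no sequence passed in limma, with a lowest adjusted p of 0.5656. The unadjusted p was under 0.05 for 5935 sequences, of which 649 were higher and 5286 lower than in the control. After centring each array on its median, 2211 were higher and 1925 lower, fewer in all than the 4780 expected by chance. The 5935 lay above that number, as did the 5581 under quantile normalization and the 7469 with only the 2 groups in the fit. Alternatives that kept all sequences gave 4082 to 8017, on both sides of it. EST FG605463 was at 8.67 ± 0.23 log2 units in the control and 12.71 ± 2.79 at 3 h (SD, n = 3 arrays). The difference was 4.04 ± 0.81 (moderated SE, adjusted p = 0.5656). Its 3 h values were 11.21, 10.98 and 15.94, the last near the ceiling of the scale at position 9, and without that array the difference was 2.43. EST FG605573 was at 8.00 ± 0.11 in the control and 10.40 ± 0.41 at 3 h (SD, n = 3 arrays), a difference of 2.39 ± 0.52 (SE, adjusted p = 0.797). It was not above the random probes on any control array, and its mean at 3 h was at least 3.1-fold higher. Read 57366 differed by -3.71 ± 0.68 and EST FG604499 by -3.62 ± 0.69, both with an adjusted p of 0.5656. Without the control array at position 3, read 57366 differed by -2.83. EST FG604499 was not above the random probes on any 3 h array, and its control mean was at least 10-fold higher. Its control values were 13.53, 9.57 and 12.34, and without the control array at position 1 the measured difference was -2.76. EST FG604499 passed only when the control array at position 2 was left out, with a difference of -4.74 and an adjusted p of 0.00506. Under the other alternatives tested the adjusted p was 0.193 to 0.9999. In the authors' deposited table the 4 differences were 0.33, 1.35, -1.0 and -2.42 in the same order.

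At 12 h no sequence passed in limma either, with a lowest adjusted p of 0.8129. Of 5817 sequences with an unadjusted p under 0.05, 2414 were higher and 3403 lower than in the control. After centring the order turned, with 3955 higher and 1894 lower. The totals, 5817 and 5849 after centring, were above the 4780 expected by chance, as was the 5064 with only the 2 groups in the fit. Alternatives that kept all sequences gave 4502 to 7508, on both sides of that number. Read 24376 was at 7.94 ± 0.39 log2 units in the control and 10.61 ± 0.59 at 12 h (SD, n = 3 arrays), a difference of 2.68 ± 0.52 (SE). It was not above the random probes on any control array, and its mean at 12 h was at least 3.6-fold higher. Read 24930 differed by 2.70 ± 0.58. Read 32281 was at 11.57 ± 1.68 in the control and 8.31 ± 0.35 at 12 h (SD, n = 3 arrays), a difference of -3.26 ± 0.63, and read 57366 differed by -3.33 ± 0.68. Without the control array at position 3, reads 32281 and 57366 differed by -2.3 and -2.45. With all arrays, all 4 reads had an adjusted p of 0.8129. Their differences in the authors' deposited table, where the 12 h column rests on the same arrays, were 2.37, 2.24, -1.40 and -1.19 in the same order. Read 57366 was among the 2 lowest at all 3 times, and the 3 comparisons share the same control arrays. Leaving out the 12 h array at position 12 gave 1 call, read 58504, which was noticed only then and had a difference of 4.80 without that array and 3.02 with it.

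Between time points no sequence passed in limma for 3 h against 0 h, 12 h against 3 h or 12 h against 0 h, where 4593, 6787 and 6125 sequences had an unadjusted p under 0.05 against 4780 expected. With only the groups compared in the fit, the count for 3 h against 0 h rose to 4929, above the number expected. It was 4781 for 12 h against 3 h, 1 above that number, and 4425 for 12 h against 0 h, below it. The moderated F test for any difference between the 4 groups called 0 sequences, with a lowest adjusted p of 0.392 and 5252 sequences under an unadjusted p of 0.05. EST FG605463 passed under quantile normalization for 3 h against 0 h (4.67) and for 12 h against 3 h (-4.62), but not in the fit of the values as deposited, where the differences were 4.85 and -4.77 and the adjusted p 0.257 and 0.166. Both differences include the 3 h value near the ceiling. EST FG605463 was not above the random probes on any 0 h or 12 h array, so these are measured values only, with no exact fold. No bound was computed between time points. Without the 12 h array at position 10, 1 sequence passed in limma for 3 h against 0 h, EST FG605463 again (4.85, adjusted p = 0.0275). That array is in neither of these groups, so only the spread estimated in the fit changed. In that fit 6 passed for 12 h against 3 h and 3 for 12 h against 0 h. Without the 12 h array at position 12, the last 2 comparisons gave 2 and 3. With no call at any time against control, 0 were shared between times.

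A 2-fold threshold with no test separated many sequences, in numbers that depended on the scaling and on single arrays. At 0 h 1457 sequences were at least 2-fold higher and 6269 at least 2-fold lower than the control. At 3 h the numbers were 1575 and 8709, and at 12 h 5069 and 5879. The total at 0 h was 7726, and became 12240 without the 0 h array at position 4 and 13796 without the one at position 6. The total at 12 h was 10948, and became 16853 without the 12 h array at position 11. The control arrays were brighter on average. The median log2 intensity was 8.77 ± 0.16 in the control, 8.56 ± 0.12 at 0 h, 8.50 ± 0.06 at 3 h and 8.61 ± 0.11 at 12 h (SD, n = 3 arrays). The control array at position 3, at 8.598, was not brighter than positions 4 and 6 at 0 h (8.608 and 8.657) or 11 and 12 at 12 h (8.654 and 8.689). The median difference from the control was -0.20, -0.26 and -0.12 log2 units at 0, 3 and 12 h. After centring each array on its median, the numbers became 3209 higher and 2965 lower at 0 h, 4161 and 3382 at 3 h, and 7427 and 3308 at 12 h. Sequences whose 3 arrays did not overlap the control's made up 11%, 14.1% and 11.7% at 0, 3 and 12 h, and 10%, 11.4% and 11.1% after centring, where chance gives 10%. The authors' deposited table gave 4302 sequences at least 2-fold higher and 4295 lower at 0 h, 4407 and 4333 at 3 h, and 4721 and 4504 at 12 h. Across sequences, its differences correlated with those from the array files at r = -0.198 for 0 h, 0.337 for 3 h and 0.695 for 12 h. These values are largely set by which arrays the sources share or place in different groups, so they do not measure agreement. The control arrays at positions 2 and 3 count as 0 h in the deposited table, while all 3 of the 12 h arrays are common to both.

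EST FG602734 and EST FG604964 recurred most often among the bright sequences, and were singled out after their values were seen. Each was among the brightest 1% of sequences on 11 of the 12 arrays, the exception being the 12 h array at position 10. FG602734 had a mean of 11.61 ± 0.21 log2 units and FG604964 of 11.61 ± 0.42 over the 12 arrays (SD). Each rests on 1 probe, so these levels do not rank the transcripts against others. FG602734 was at 11.66 ± 0.04 in the control, 11.75 ± 0.38 at 0 h, 11.58 ± 0.11 at 3 h and 11.45 ± 0.12 at 12 h (SD, n = 3 arrays). Its differences from the control were 0.09, -0.08 and -0.22 with a moderated SE of 0.48, to which the spread of other sequences contributes. FG604964 was at 11.69 ± 0.24, 11.55 ± 0.77, 11.44 ± 0.36 and 11.78 ± 0.33 in the same order (SD, n = 3 arrays). The differences of FG604964 were -0.14, -0.25 and 0.09 with a moderated SE of 0.52. The adjusted p in limma was 0.9579 or above for both at all 3 times. The signs of these differences depend on the scaling: after centring, those of FG602734 were 0.29, 0.19 and -0.06, and those of FG604964 were 0.06, 0.02 and 0.25.

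**Figure D4:**
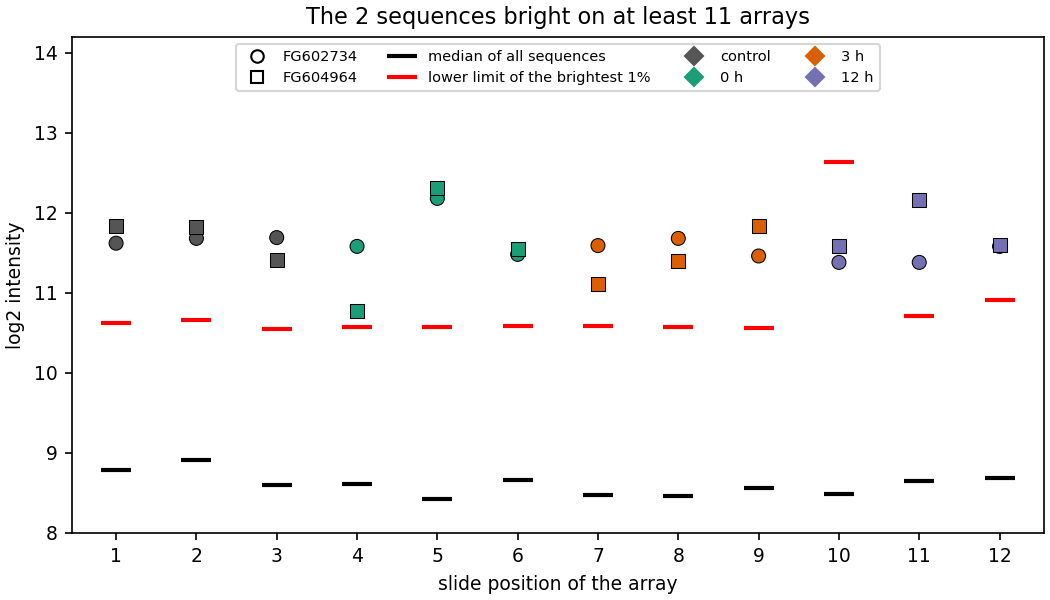
Log2 intensity of EST FG602734 (circles) and EST FG604964 (squares) on each array by slide position, coloured by group, with the array's median (black) and the lower limit of its brightest 1% of sequences (red). Both lie above that limit on every array except the one at position 10, and their means over the 12 arrays are both 11.61.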

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

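No sequence passed for 0 h against control under any alternative. Quantile normalization gave 1 sequence for 3 h against 0 h, 1 for 12 h against 3 h and 1 in the test of any difference, EST FG605463 in both pairwise comparisons. Slide position as a covariate gave 1 sequence in the test of any difference. Leaving out each array in turn gave 0 to 1 sequences for 3 h and for 12 h against control, with or without the 2-fold limit, 0 to 1 for 3 h against 0 h, 0 to 6 for 12 h against 3 h, 0 to 3 for 12 h against 0 h and 0 to 3 for any difference. The arrays concerned were the control array at position 2 and the 12 h arrays at positions 10 and 12. Each sequence so gained in a pairwise comparison had an adjusted p of 0.257 or above with all arrays. For EST FG605463 in 3 h against 0 h, the array left out at position 10 is in neither group. The difference stayed at 4.85, so only the spread estimated in the fit changed, and the adjusted p went from 0.257 to 0.0275. The cause of the other calls gained under these alternatives was not tested. Median centring, both filters, the trended prior, array weights, fitting only the groups compared, the stricter threshold and the deposited table's grouping, with or without quantile normalization, gave 0 in every comparison they were run on. Under the table's grouping the difference at 0 h was reversed for read 96977 (-1.27, and -1.65 with quantile normalization; -1.76 in the deposited table), read 34882 (1.18, 1.17 and 1.40) and read 57366 (2.0, 0.94 and 0.89). It was reversed for read 52637 with quantile normalization (-0.04), and at 3 h for EST FG605463 without it (-0.36, against 0.17 with it). The table's grouping moves control arrays into 0 h, which by construction can turn a sign. Slide position as a covariate reversed EST FG605463 at 3 h (-0.84) and moved reads 52637 and 57366 at 0 h to 4.36 and -5.2. It moved EST FG604499 and read 57366 at 3 h to -0.94 and -7.07, and reads 57366, 32281 and 24930 at 12 h to -8.36, -7.69 and 1.76. With that covariate 29424, 52448 and 64516 sequences were at least 2-fold apart at 0, 3 and 12 h against 7726, 10284 and 10948 without it, as position and group are nearly collinear. Leaving out single arrays gave up to 13796 at 0 h and 16853 at 12 h. Testing only sequences above the median gave 4716, 6041 and 7282 at least 2-fold apart and 1749, 2535 and 2929 (2175, 3586 and 3271 for 3 h against 0 h, 12 h against 3 h and 12 h against 0 h) with an unadjusted p under 0.05, from fewer sequences. At that p, alternatives that kept all sequences gave 2536 (without the 0 h array at position 5) to 5711 at 0 h. They gave 4082 to 8017 at 3 h and 4502 to 7508 at 12 h. Between times they gave 3515 to 5722, 4556 to 8215 and 4330 to 7653 in the same order. Each range includes the 4780 expected by chance. For 12 h against 3 h, only the deposited table's grouping with quantile normalization fell below it, at 4556. Alternatives that kept the grouping by file gave 4781 or more there. Averaging per gene and the tests of gene lists were not run, since no identifier could be named. The array medians lie at the random probes, and with the spread between arrays only 20% of simulated 4-fold changes were recovered at 12 h. No paired analysis was possible because the labels give the arrays no replicate numbers.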

Other observations

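All tests in this part were chosen after the array values had been seen, apart from the counts of sequences past the adjusted threshold. A few more sequences than EST FG602734 and EST FG604964 recurred among the brightest 1% of arrays. If arrays were unrelated, 0.44 sequences would be expected in the brightest 1% on 4 or more arrays, and 29 were found; on 3 or more, 110 were found against 19.7. Reads 3887, 57426 and 65895 reached it on 6 arrays each. Read 3887 ranged from 7.54 to 12.14 log2 units over the 12 arrays and varied within every group, with SDs of 1.66, 1.87, 2.53 and 1.43 for control, 0 h, 3 h and 12 h. The first principal component of the ranked arrays held 11.4% of the variance, where 12 unrelated arrays give 8.3%.

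The lack of likeness between arrays bears on every comparison, though whether it accounts for the absence of calls was not tested. A per-array step of the authors' normalization is argued against as the cause of the low likeness. A step that keeps the order within an array leaves ranks alone, and the median rank correlation was 0.031 as well. A constant shift of rows between the files is argued against too: over 95607 offsets per pair of arrays, the highest absolute rank correlation at a non-zero offset was 0.016. Signal at the level of the random control probes remains a candidate. The largest gap between an array's median and its random probes was 0.018 log2 units, but it had been seen beforehand and describes medians only. On each array 7.28% to 18.27% of the sequences lay at least 2-fold above the random probes. Of 10417 sequences in the brightest 1% on any array, 905 were so on 2 or more, against 590.3 expected for unrelated arrays. Why bright sequences so rarely recurred was not tested. Sequence names mixed up in the same way on all arrays would leave the correlation between arrays as it is, so they cannot cause this pattern. A misplaced grid or a mix-up that differed between arrays could, and would also put sequences and random probes at 1 level. Neither can be told apart from weak hybridisation here. The 2 ESTs that were bright on 11 arrays argue against a complete mix-up of this kind, but they are too few to exclude one that spared some probes. No biological explanation was tested, since the pattern spans all groups.

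The absence of calls may also be thought to come from array files attached to other samples than the value table's, given that 5 of the 12 arrays change group between the sources. Grouped as in the table, 0 sequences passed in any comparison, so this regrouping alone did not bring calls. As the test recovered only 20% of simulated 4-fold changes, calls could also be missing under a correct grouping. Arrays of a sample then had a mean rank correlation of 0.0322. That value cannot decide the question, since no pair of arrays exceeded 0.104 and no grouping could have given a high mean. Which assignment is correct stays open. It matters for any reading by fold alone, since a sign can turn with the grouping. Of the sequences at least 2-fold apart in the deposited table, 37.2% had the same sign in the array files at 0 h. The share was 76.2% at 3 h and 96.7% at 12 h. These shares follow largely from the arrays that the groupings have in common or swap, and the sequences were picked by their size in the deposited table. They do not measure how well a difference held.

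Arrays of a sample were on average slightly more alike than others when grouped by file, but not evenly over the groups. The rho of the 3 pairs was 0.099, 0.062 and 0.049 in the control and 0.046, 0.048 and 0.045 at 0 h. It was 0.027, 0.048 and 0.014 at 3 h and 0.027, -0.023 and 0.058 at 12 h. The highest rho of all, 0.104, joined the control array at position 2 and the 0 h array at position 6. Nearness on the slide may account for the excess within samples, since likeness fell with distance (rank correlation -0.31). The shared sample is the biological candidate: pairs at most 2 positions apart had a mean rho of 0.0417 within a sample and 0.0315 between samples. Under the table's grouping the means were 0.0309 within and 0.0422 between. Position and sample cannot be told apart: by file each sample fills neighbouring positions, and under the table's grouping, where the control lies at positions 1, 5 and 9, the order is the opposite.

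The arrays were also split in other ways, counting the real split among the splits. Where the observed count past the adjusted threshold was 0, no split can give fewer, so all 10 of the 10 splits of each pairwise comparison, with or without a 2-fold limit, and all 100 of the 100 splits for any difference gave as many by construction and decide nothing. The highest other count was 1 for 3 h against 0 h, for 12 h against 3 h and for any difference, and 0 for the rest. For the sequences with an unadjusted p under 0.05, as many as observed came from 2 splits at 0 h (3979, highest other 4996), 1 split at 3 h (5935, highest other 4727) and 2 splits at 12 h (5817, highest other 5899). For the sequences at least 2-fold apart, it was 2 splits at 0 h (7726, highest other 9040), 1 at 3 h (10284, highest other 9086) and 2 at 12 h (10948, highest other 11154). After centring each array on its median it was 4 splits at 0 h (6174, highest other 6662), 1 at 3 h (7543, highest other 7281) and 1 at 12 h (10735, highest other 9840). With 10 splits of 6 arrays there are too few for a share under 0.05. The covariance between the log2 differences from control at different times, which shared control arrays raise without any effect, was 0.1406 for 0 and 3 h, 0.1477 for 0 and 12 h and 0.1637 for 3 and 12 h, against 0.1676, 0.1674 and 0.1677 in simulated unchanged groups. The simulation gave every group the same spread. The middle 50% of sequences spanned 0.769 to 0.879 log2 units on the control arrays and 0.772 to 1.231 on the others. Values below the simulated ones therefore do not exclude a shared effect.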
